A study of Mus musculus with 40 samples.

How the data were processed

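Poly(A) RNA from mouse liver was sequenced in 40 libraries, per the labels' protocols. All libraries carry the strain label C57BL/6NCrl. The authors deposited whole-number read counts per gene, 1 table per library, with 57186 Ensembl gene IDs each. STAR 2.7.10b, featureCounts 2.0.6 and the mm39 build are named in the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and reads of near-identical copies may have been divided or dropped. Gene symbols came from a table of gene names that matched 51880 IDs (90.7%), which held 99.7% of all counts. The reference used for symbols, for which genes neighbour Nnt and for which models lie inside others was GENCODE M21 on the earlier mouse build GRCm38, so no coordinates are given. Its gene models can differ from those the authors counted on.

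Libraries were grouped by the genotype, sex and diet in their titles. The treatment label disagrees with the titles for 20 of 40 libraries. Under it every WT library would be chow and every KO library HFD, which would leave genotype and diet inseparable, whereas the described design switched part of the mice of both sexes to HFD without naming a genotype. The column names carry 1 sequencing lane code in all libraries, so no batch could be separated.

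Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group, which left 15627, and library sizes were scaled by TMM. A single fit of 8 group means over 40 libraries gave 14 contrasts by the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called at an adjusted p under 0.05. Log2 differences are edgeR's and the error after ± is their standard error, taken as the size of the log2 difference divided by the square root of F. CPM values use the TMM-scaled library size, except those of Nnt and of the check of sex labels, which use the unscaled library total, and errors of CPM are SD over 5 libraries. Intervals are at the 95% level, and a count of 0 is read as at most 3 counts. Both cover counting error and spread between these libraries only.

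The 39 gene lists tested were metabolic pathways, stress and immune responses, markers of liver cell types and of other tissues, sex-biased and clock genes, and checks of substrain and sex. Each was tested against the other genes with limma 3.58.1 camera at a preset correlation of 0.01, adjusted over the 39 lists of a contrast. Camera with a correlation estimated from the data and fry were the alternatives. Fry tests a list against no change, not against the other genes. Members were also counted with p-values adjusted over the list alone. With the preset correlation 188 list calls were made over the 14 contrasts, of which 16 held with an estimated correlation. Of the 188, 48 also had a fry adjusted p under 0.05 in the same direction.

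The groups, contrasts, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule named Nnt, and for each genotype and diet contrast the 6 genes with the largest and the 6 with the smallest log2 difference among called genes with a mean of at least 1 CPM, an assigned symbol and no overlap between the libraries compared. It also named up to 3 called members of each list with at least 3 called members or a list adjusted p under 0.05, all calls where there were 10 or fewer, the 6 interaction genes of smallest adjusted p, and called genes within 5 Mb of Nnt. The text gives those of most use to each comparison. Genes called only by another tool or setting were named after their values were seen.

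The alternatives were RLE size factors, no low-count filter, a filter of at least 1 CPM in at least 5 libraries, a 2-fold threshold, DESeq2 1.42.0, only the groups compared, a replicate block and each library left out in turn. A covariate built from clock genes and the naming of KO male chow replicate 3 as a doubted library were added after seeing the data. Other splits of the samples were drawn at most 100 times per result, the real one included.

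The calls were tested on simulated counts with known changes, 50 genes per fold. All folds were simulated together and genes were drawn independently of each other. Where fewer genes change, the adjusted threshold is stricter and fewer small changes are recovered. The rates below are therefore not the power of the genotype contrasts, which called 0 or 1 gene. For a change in 1 KO group, a contrast of 2 groups recovered 14% of 1.25-fold, 68% of 1.5-fold, 78% of 2-fold and 94% of 4-fold changes among 15412 genes, with 8 false calls. For a change in all 4 KO groups, the mean over the strata recovered 64%, 86%, 92% and 98% among 15418 genes, with 12 false calls. An interaction in females recovered 10%, 44%, 64% and 80% among 15430 genes, with 2 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.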

Results

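Liver RNA from mice labelled as with and without functional NNT was sequenced after poly(A) selection. NNT is nicotinamide nucleotide transhydrogenase, an enzyme of the inner mitochondrial membrane that makes NADPH, and Nnt is its gene. The 40 libraries formed 8 groups of 5, from 2 genotypes (WT and KO), 2 sexes and 2 diets. The mice were 22 to 24 weeks old, and the high fat diet (HFD, 45 kcal% fat) had been fed for 11 weeks in place of chow. Chow was the only other diet, so HFD effects below are differences between 2 feeds. An effect of fat cannot be told apart from other differences between them. Livers were taken 2 to 4.5 h after lights on. The total count per library, in 1e6 counts (M), ran from 15.97 to 28.16 M, with a median of 20.43 M. Group means ran from 17.7 M in KO males on chow to 22.3 M in WT females on HFD. The labels number the libraries of a group as replicates without tying each to a mouse, so p-values measure the spread between these libraries. The smallest difference between replicates was a chi-square of 7.98 per degree of freedom over 80 pairs, and 0 pairs held identical counts. The titles give both diets in each genotype, whereas the treatment label gives chow for every WT library and HFD for every KO library. The titles and that label differed for 20 of 40 libraries, and the diet in the titles was used. Between the diets in the titles, within each genotype and sex, 438 to 1811 genes differed, against 0 or 1 between genotypes. Under the treatment label the diets would part the genotypes instead, so these counts argue against that label.

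Nnt (ENSMUSG00000025453), the gene the genotypes refer to, was near the floor in all 8 groups and alike in WT and KO libraries. Each library held 13 to 54 Nnt reads, at most 2.13 CPM (counts per 1e6 counts). In females on chow, Nnt was at 1.40 ± 0.60 CPM in WT and 1.44 ± 0.30 CPM in KO libraries (mean ± SD, n = 5 each). In males on chow it was at 1.29 ± 0.33 and 1.5 ± 0.39 CPM, in females on HFD at 1.30 ± 0.21 and 1.23 ± 0.35 CPM, and in males on HFD at 1.40 ± 0.27 and 1.16 ± 0.44 CPM. The KO minus WT log2 difference averaged over the 4 strata of sex and diet was -0.05 ± 0.13 (95% interval -0.32 to 0.22). A second gene model named Nnt (ENSMUSG00000116207) held 0 reads in each of the 40 libraries, which allows at most 3 reads per library. In the GENCODE M21 annotation, the 3339 exonic bases of that second model lie wholly inside the 7037 exonic bases of the first. The deposited counts therefore gave no check of the genotype labels, and WT and KO below are the groups as labelled. Of the genes within 5 Mb of Nnt in that annotation, 21 were tested, and 0 differed between genotypes in any of the 4 strata or in their mean (edgeR; 1, 1, 2, 1 and 2 of them had an unadjusted p under 0.05).

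**Figure D1:**
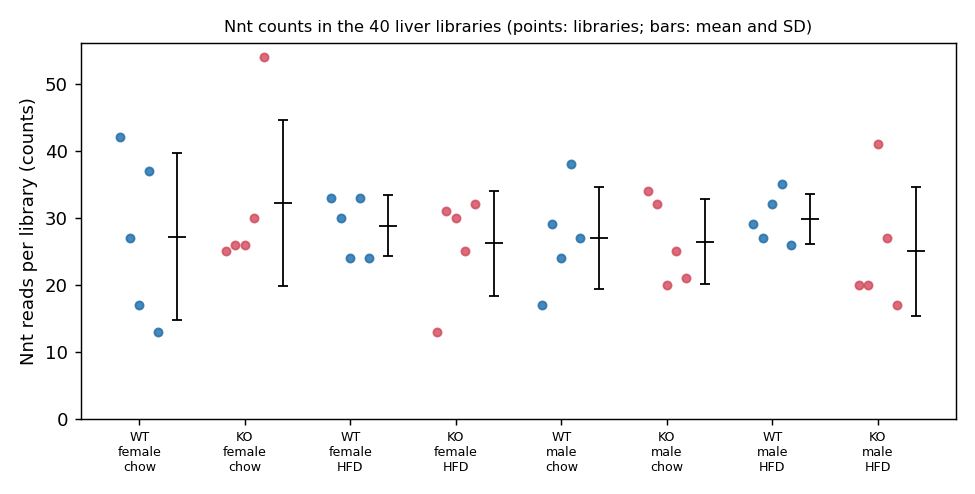
Nnt reads per library (counts, vertical axis) in the 8 groups (horizontal axis); blue points are WT libraries, red points are KO libraries, and bars give the mean and SD of 5 libraries. Values run from 13 to 54 reads, and WT and KO libraries overlap in each stratum.

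Genes of the sex chromosomes matched the sex in the labels. Xist, the X-linked RNA expressed in females, was at 1226 to 1765 CPM in the 20 female libraries and at most 2.47 CPM in the 20 male libraries. The Y-linked gene Ddx3y had 0 reads in females and 95.8 to 136 CPM in males. Over the 500 most variable genes, the first principal component held 74.6% of the variance and separated females (-42.9 to -29.9) from males (20 to 46.9). The second held 8.76% and ranged from -20.5 to 3.14 in chow libraries and from -3.83 to 27.1 in HFD libraries. The highest chow value was that of WT male chow replicate 3, the other chow libraries being at most -4.29. The lowest HFD value was that of KO male HFD replicate 2, the other HFD libraries being at least 0.97.

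The comparison of KO with WT asks what loss of functional NNT does to liver expression, provided the genotype labels hold, which the counts could not show. Of 15627 genes tested, 1 differed between genotypes in any stratum. Ttbk2 (ENSMUSG00000090100), which encodes tau tubulin kinase 2, was higher in KO than in WT females on HFD, at 9.76 against 6.91 CPM (log2 difference 0.50 ± 0.08, edgeR adjusted p = 0.0143). Its call was lost without WT female HFD replicate 2, 3 or 4 or without KO female HFD replicate 1, 3 or 4, where the adjusted p reached 0.15. It was also lost with no low-count filter and when only those groups entered the fit. The edgeR quasi-likelihood test called 0 genes in females on chow, in males on chow, in males on HFD and for the mean over the 4 strata. In that order, 698 (4.47%), 1323 (8.47%), 1088 (6.96%) and 1044 (6.68%) of the genes had an unadjusted p under 0.05. A share of 0.05 is expected if no gene differs, and the cause of the larger shares was not tested. DESeq2 called 0 and 0 in females on chow and males on HFD. It called Rgs16 in males on chow (-3.52 ± 0.71, adjusted p = 0.0196) and Hao2 in the mean (-1.74 ± 0.32, adjusted p = 0.00239). In males on HFD edgeR called Cyp3a11 and Cyp2b13 without WT male HFD replicate 2, and 6 genes without WT male HFD replicate 4. With no low-count filter, Cyp2b13 (-2.23 ± 0.42) and Atp2a1 (5.73 ± 1.06) were called in males on HFD.

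Enzymes that supply NADPH or remove peroxides had no called difference between genotypes over all genes tested. Of the 19 measured NADPH-producing enzymes other than Nnt, 0 differed in the mean over the 4 strata over all genes tested, and 0 adjusted over the list alone. Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, had a KO minus WT log2 difference of -0.19 ± 0.06 (95% interval -0.31 to -0.06), with an adjusted p of 0.612. In males on HFD Idh2 had -0.41 ± 0.12 (95% interval -0.67 to -0.16), with an adjusted p of 0.463 over all genes tested, and was the 1 enzyme of 19 lower in KO adjusted over the list alone, against 0 in each of the other 3 strata. G6pdx, which opens the pentose phosphate pathway, had 0.02 ± 0.16 (95% interval -0.31 to 0.35) and Me1, cytosolic malic enzyme, 0.11 ± 0.14 (95% interval -0.18 to 0.39). Of the 26 genes of glutathione, thioredoxin and peroxide removal, 0 differed, and glutathione reductase (Gsr) had -0.07 ± 0.03 (95% interval -0.13 to -0.01). The NRF2 targets (29 measured) had a median log2 difference of -0.06 with 0 changed. Of 5 measured genes known to differ between C57BL/6J and C57BL/6N mice, 0 differed, and Wdfy1 had 0.01 ± 0.04 (95% interval -0.07 to 0.10).

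Gene groups of mitochondria and of sex-dependent metabolism had shifts between genotypes that varied over the strata. Their list calls rested on the assumed correlation between genes. In the mean over the 4 strata, 0 of 56 nuclear respiratory chain genes were called, with a median log2 difference of -0.07 and 9 lower when adjusted over the list alone. Among 32 genes of fatty acid oxidation and PPARA targets (PPARA is the fatty acid receptor of hepatocytes) the median was -0.14, with 8 lower adjusted over the list alone. Among 24 female-biased liver genes it was -0.55, with 6 lower adjusted over the list alone, and among 26 male-biased genes 0.30 with 0. The female-biased median was -0.76 and -0.75 in males on chow and HFD, against -0.07 and -0.12 in females. In males on HFD, 14 of these 24 genes were under 1% of their level in females on HFD. The male-biased median was 0.60 in males on HFD and 0.17 on chow, against -0.02 and 0.19 in females. For oxidation it was 0.04 in females on HFD and -0.19 to -0.16 in the other strata. For genotype by sex, 0 lists were called with an estimated correlation. limma's camera with a preset correlation of 0.01 called 12, 17, 9, 15 and 15 of 39 lists in females on chow, males on chow, females on HFD, males on HFD and the mean. With an estimated correlation it called 0 in each, and fry called 0 in each. For the respiratory chain, fatty acid oxidation, female-biased and male-biased lists in the mean, adjusted p = 0.280, 0.280, 0.280 and 0.280 with an estimated correlation. Of 13 mitochondrially encoded genes, 8 were lower in KO than WT males on chow adjusted over the list alone and 0 over all genes. For that list the adjusted p was 0.208 with an estimated correlation and 0.0539 with fry. KO male chow replicate 3 had a mitochondrial share of 4.02%, against 7.32% to 7.93% in the other 4 libraries of its group. Those 4 were also below the WT male chow libraries, at 7.96% to 8.76%.

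**Figure D2:**
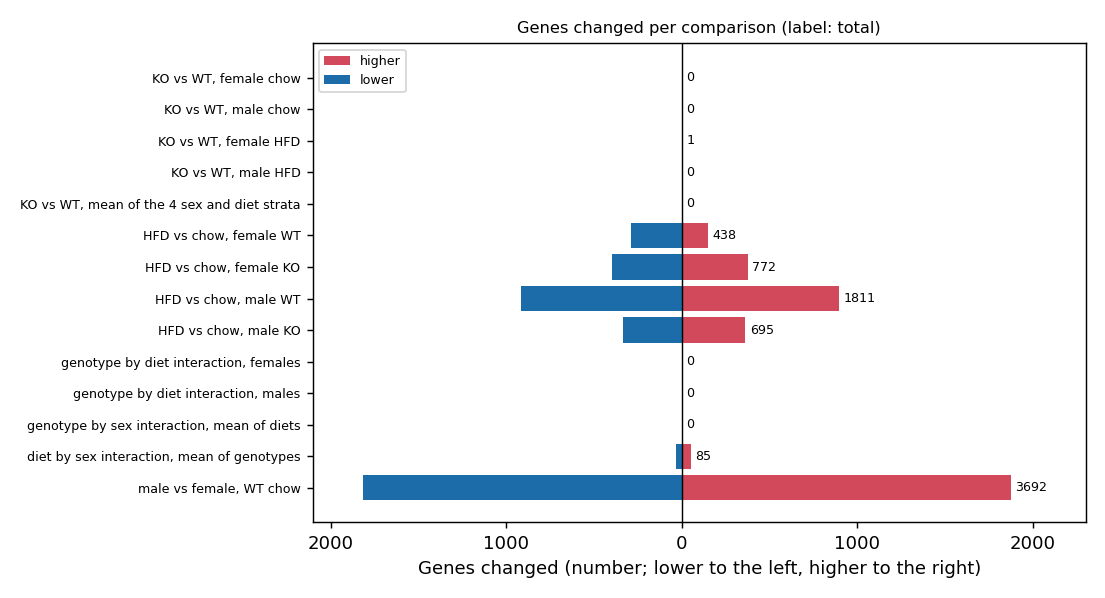
Number of genes higher (red, to the right) and lower (blue, to the left) at an edgeR adjusted p under 0.05 in each of 14 comparisons (vertical axis), with the total beside each bar. Genotype comparisons have 0 or 1 gene and diet comparisons 438 to 1811.

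In WT females, HFD lowered cytochrome P450 genes of xenobiotic metabolism and nearly the whole set of cholesterol synthesis genes. Cyp2b10 (ENSMUSG00000030483), a cytochrome P450 induced by foreign compounds, went from 124 ± 36.8 to 6.57 ± 3.36 CPM (mean ± SD, n = 5), 18.8-fold lower (log2 -4.24 ± 0.36, adjusted p = 6.18e-10). Cyp2c29 fell by 1.35 and the carboxylesterase Ces2a by 0.99 on the log2 scale. In total 10 of 21 xenobiotic genes fell and 0 rose. Of 23 cholesterol genes, 19 fell, among them Msmo1 (-1.55 ± 0.20), the squalene synthase Fdft1 (-1.21 ± 0.17) and the HMG-CoA synthase Hmgcs1 (-1.22 ± 0.22). Both lists kept their call with an estimated correlation (adjusted p = 9.04e-04 and 0.00438).

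Fewer genes of fat handling rose in WT females. Of 32 fatty acid oxidation genes 3 rose, among them Cpt1a, which brings fatty acids into mitochondria (0.65 ± 0.13), and of 22 lipid droplet genes 3 rose. The lipoprotein lipase gene Lpl had 1.35 ± 0.28. It was at 141.9 CPM in WT female HFD replicate 2 against 30.4 to 47.2 CPM in the others, and without that library it had 0.74 (adjusted p = 0.0502). Plin4, a lipid droplet coat protein, had 1.85 ± 0.44, and lost its call without WT female HFD replicate 1 (adjusted p = 0.0577). With an estimated correlation the adjusted p was 0.501 for oxidation and 0.444 for lipid droplets. In bile acid metabolism, 3 of 22 genes fell and 2 rose (estimated correlation, adjusted p = 0.0291). Cyp27a1, a sterol hydroxylase of bile acid synthesis, had -0.50 ± 0.09, the exporter Abcc4 -1.34 ± 0.26, and Abcg8, part of the sterol exporter to bile, 0.98 ± 0.20. Of 24 female-biased genes 7 fell, among them Sult3a1 (-2.25 ± 0.41) and A1bg (-2.07 ± 0.37), with adjusted p = 0.361 with an estimated correlation. The pericentral genes Cyp2c37 (-0.97 ± 0.16) and Cyp1a2 (-0.98 ± 0.20) also fell, as did the periportal gene Cyp2f2 (-0.80 ± 0.14). Outside the lists, the extremes included Slc34a2 (-4.06 ± 0.59), Clic3 (-3.06 ± 0.51), Eci3 (-2.48 ± 0.33) and Kcnk10 (1.36 ± 0.26). Over all genes 438 changed, 150 higher and 288 lower. The count was 289 without WT female chow replicate 5, 234 without WT female HFD replicate 2, 226 when only those groups entered the fit, and 126 at 2-fold or more. Of 44 named genes, 26 kept their call whichever library was left out, and Lpl, Cyp27a1, Sult3a1 and A1bg lost theirs when only those groups entered the fit.

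In KO females, HFD lowered xenobiotic and cholesterol genes as well, and raised genes of lipid storage. Cyp2b10 went from 118 ± 36.8 to 4.5 ± 1.88 CPM (-4.71 ± 0.37, adjusted p = 7.07e-11), and 9 of 21 xenobiotic genes fell, with Ces2a at -1.51 ± 0.14 and Cyp2c29 at -1.38 ± 0.13. Of 23 cholesterol genes 16 fell, with Fdft1 at -0.97 ± 0.17, Msmo1 at -0.96 ± 0.20 and Tm7sf2 at -0.85 ± 0.14. Of 22 lipid droplet genes 11 rose, including Plin4 (3.0 ± 0.43), Hsd17b13 (0.89 ± 0.11) and Fitm2 (0.64 ± 0.12), and Mogat1, which makes diacylglycerol, had 2.83 ± 0.66. These 3 lists kept their calls with an estimated correlation (adjusted p = 0.00174, 0.0480 and 0.0350).

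Of 32 oxidation genes 14 rose in KO females, among them Cpt1a (0.79 ± 0.13), Etfdh (0.35 ± 0.07) and the hepatokine Fgf21 (2.81 ± 0.47), with adjusted p = 0.171 with an estimated correlation. Pericentral genes fell in 5 of 20 cases, among them Cyp1a2 (-1.64 ± 0.20), Cyp2c37 (-0.94 ± 0.16) and Rgn (-0.41 ± 0.08), and that list kept its call (estimated correlation, adjusted p = 0.0480). In bile acid metabolism 6 of 22 genes fell, among them Cyp27a1 (-0.61 ± 0.09), Slc27a5 (-0.38 ± 0.07) and the bile salt export pump Abcb11 (-0.49 ± 0.09), with adjusted p = 0.0603 with an estimated correlation. Of 20 fatty acid synthesis genes 3 fell, including the transcription factor gene Mlxipl (-0.65 ± 0.10) and Acss2 (-1.53 ± 0.36), and 1 rose (adjusted p = 0.605 with an estimated correlation). Lactate dehydrogenase (Ldha) had 0.62 ± 0.12. Female-biased genes fell in 7 of 24 cases, among them Cyp3a44 (-2.68 ± 0.48) and A1bg (-1.86 ± 0.37), with adjusted p = 0.357 with an estimated correlation. Over all genes 772 changed, 375 higher and 397 lower, and 216 at 2-fold or more. Of 55 named genes, 41 kept their call whichever library was left out, and A1bg lost its call with DESeq2.

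In WT males, the fall of cholesterol synthesis on HFD took in 22 of 23 genes and was accompanied by a rise of fatty acid oxidation and lipid droplet genes. Squalene epoxidase (Sqle) went from 136 ± 38.1 to 16.9 ± 7.06 CPM (-3.0 ± 0.33, adjusted p = 1.36e-07), Msmo1 had -1.82 ± 0.20 and Fdft1 -1.61 ± 0.17. The cholesterol list kept its call (estimated correlation, adjusted p = 0.00309). Oxidation genes rose in 22 of 32 cases, including Cpt1a (0.86 ± 0.13), Hadh (0.54 ± 0.10) and Hadhb (0.53 ± 0.10), and lipid droplet genes in 13 of 22, including Plin4 (3.04 ± 0.42) and Cidec (2.63 ± 0.40). With an estimated correlation these lists had an adjusted p of 0.106 and 0.0799. Cidec is also among 5 adipose markers, of which 3 rose and 1 fell. Xenobiotic genes fell in 8 of 21 cases and rose in 1 (adjusted p = 0.0799 with an estimated correlation), with Cyp2b10 going from 34.8 ± 12.8 to 2.12 ± 0.966 CPM, Cyp2c29 at -1.63 ± 0.13 and Cyp2c55 at -2.61 ± 0.29.

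Sex-biased genes moved in WT males on HFD. Of 26 male-biased genes 16 fell and 0 rose, among them Ugt2b38 (-3.37 ± 0.54), Susd4 (-1.50 ± 0.27) and Nudt7 (-1.40 ± 0.25), with adjusted p = 0.0894 with an estimated correlation. Of 24 female-biased genes 8 rose and 2 fell (adjusted p = 0.381 with an estimated correlation). Cyp2b9 went from 6.69 ± 7.52 to 186 ± 141 CPM (4.75 ± 0.79, adjusted p = 7.86e-05), and the peroxisomal transporter gene Abcd2 had 2.49 ± 0.41. Cyp2b13 went from 0.0508 ± 0.114 to 6.85 ± 6.02 CPM, where the chow level rests on 6 reads in 1 of 5 libraries, and Cyp2c40 fell by 3.39 on the log2 scale. Cyp2b9, Cyp2b10 and Cyp2b13 are close relatives, so reads may have been divided between them by the counting.

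Other metabolic lists moved in part in WT males. Fatty acid synthesis genes fell in 9 of 20 cases, with Acss2 at -2.18 ± 0.37, the citrate carrier Slc25a1 at -0.65 ± 0.10 and Mlxipl at -0.57 ± 0.10 (adjusted p = 0.254 with an estimated correlation). NAD metabolism genes fell in 7 of 24 cases, including Haao (-0.59 ± 0.10), Acmsd (-1.42 ± 0.29) and Nmrk1 (-0.62 ± 0.11), with adjusted p = 0.0894 with an estimated correlation. Of the 19 NADPH-producing enzymes 4 fell, including Aldh1l1 (-0.92 ± 0.15), and the list was not called (camera adjusted p = 0.0814). Bile acid genes rose in 4 cases and fell in 7 of 22, with Cyp2c70, which makes muricholic acids, at -1.32 ± 0.20 and the phospholipid exporter Abcb4 at 0.66 ± 0.11. Ldha (0.75 ± 0.12) and pyruvate carboxylase, Pcx (0.66 ± 0.11), rose. Zonation markers moved both ways, with Cyp1a2 at -1.81 ± 0.20, Aldh3a2 at 1.26 ± 0.20, Cyp2f2 at -0.77 ± 0.14 and Ass1 of the urea cycle at -0.95 ± 0.19. The extremes included Chrna4 (-5.09 ± 0.79), Adgrf1 (-4.36 ± 0.64), Rian (-3.64 ± 0.50) and the lipid droplet gene Cidea (4.08 ± 0.83). Over all genes 1811 changed, 894 higher and 917 lower, with 382 at 2-fold or more and 1079 when only those groups entered the fit. Of 83 named genes, 66 kept their call whichever library was left out.

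In KO males, HFD lowered 20 of 23 cholesterol genes and 8 of 21 xenobiotic genes, and raised 22 of 32 oxidation genes and 9 of 22 lipid droplet genes. Sqle went from 108 ± 26.1 to 11.2 ± 2.56 CPM (-3.27 ± 0.34, adjusted p = 6.88e-08), and Msmo1 had -1.77 ± 0.20. Cyp2b10 went from 33.7 ± 7.10 to 1.3 ± 0.756 CPM (-4.75 ± 0.42, adjusted p = 1.01e-09), Cyp2c29 had -1.72 ± 0.13 and Cyp2c55 -2.79 ± 0.31. Cpt1a went from 267 ± 27.4 to 575 ± 57.3 CPM (1.11 ± 0.13, adjusted p = 5.49e-07), and Vnn1, a PPARA target, had 2.29 ± 0.38. Plin4 had 2.51 ± 0.44, Cidec 2.69 ± 0.42 and Fitm2 0.69 ± 0.12. Cidec is also among 5 adipose markers, of which 2 rose, the other being Cfd (3.71 ± 0.82). All 4 lists kept their calls with an estimated correlation (adjusted p = 9.17e-04, 0.00947, 0.0448 and 0.0448 in the order given).

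Abcd2 (3.91 ± 0.48, adjusted p = 9.60e-07) and Cyp2b9 (5.28 ± 0.90, adjusted p = 2.44e-04) were among 7 of 24 female-biased genes that rose in KO males, and 2 fell, including Cyp2c40 (-2.75 ± 0.43), with adjusted p = 0.352 with an estimated correlation. Of 26 male-biased genes 3 fell, with Ugt2b38 at -2.43 ± 0.49 and Susd4 at -1.14 ± 0.26 (adjusted p = 0.333 with an estimated correlation). The sterol exporter genes Abcg5 (1.35 ± 0.22) and Abcg8 (1.30 ± 0.20) rose, as did Abcb4 (0.63 ± 0.11), in a bile acid list with 3 genes higher and 5 lower (camera adjusted p = 0.642). Glycogen synthase, Gys2 (0.53 ± 0.11), Pcx (0.53 ± 0.11) and Ldha (0.63 ± 0.12) rose among 23 glucose genes (adjusted p = 0.268 with an estimated correlation). Rgs16 had 3.88 ± 0.82, Fgf21 2.67 ± 0.48, Fabp5 -2.86 ± 0.57 and Clic3 -2.93 ± 0.52. Over all genes 695 changed, 363 higher and 332 lower, with 192 at 2-fold or more, 462 without KO male HFD replicate 3, 441 without KO male HFD replicate 5 and 496 without KO male chow replicate 3, the library of low mitochondrial share. Of 43 named genes, 36 kept their call whichever library was left out.

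**Figure D3:**
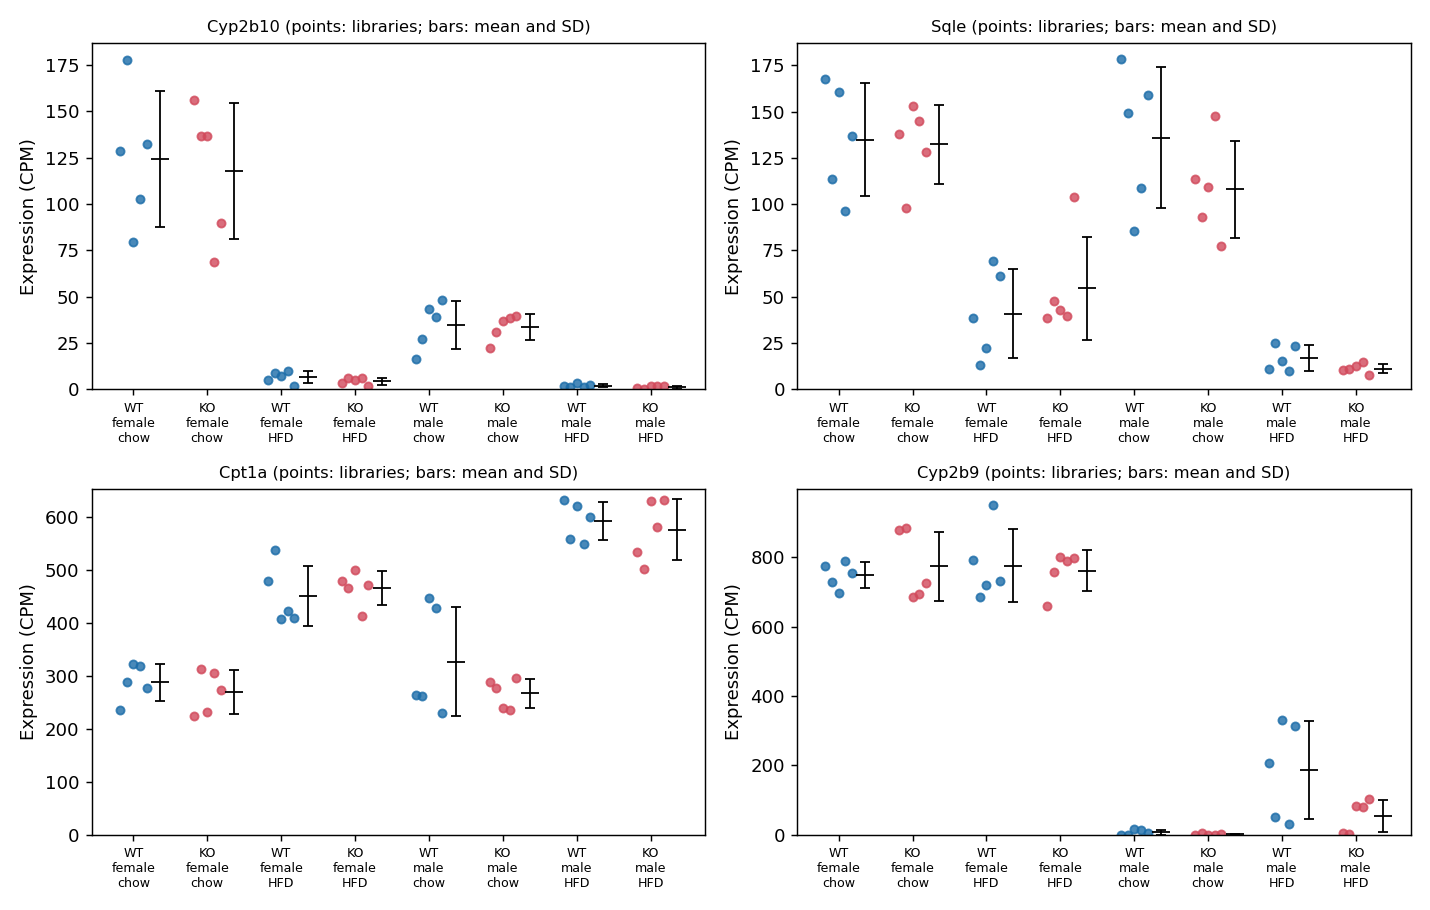
Expression (CPM, vertical axes) of Cyp2b10, Sqle, Cpt1a and Cyp2b9 in the 8 groups (horizontal axes); blue points are WT libraries, red points are KO libraries, and bars give the mean and SD of 5 libraries. Cyp2b10 and Sqle are lower and Cpt1a higher on HFD in both sexes, and Cyp2b9 in males goes from at most 16 CPM on chow to 2.15 to 329.5 CPM on HFD.

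The diet response shared many genes between genotypes, and its difference between them was tested directly. In females, 69 genes rose in both WT and KO (3.60 expected of independent lists) and 161 fell in both (7.32 expected). In males, 227 rose in both (20.8 expected) and 237 fell in both (19.5 expected). These lists share no libraries, and 0 genes changed in opposite directions. For the genotype by diet interaction, 694 genes (4.44%) in females and 1185 (7.58%) in males had an unadjusted edgeR p under 0.05. The interaction called 0 genes in females and 0 in males with edgeR, and 0 and 0 with DESeq2. Without WT male chow replicate 4 it called Iqgap1 in males, and with a clock gene score as a covariate 9 genes in males, 6 of them clock genes. The larger count in WT than in KO males, 1811 against 695, is therefore not by itself a difference between genotypes. For the genotype by sex interaction over both diets, 1245 genes (7.97%) had an unadjusted edgeR p under 0.05. This interaction called 0 genes with edgeR and 13 with DESeq2, including Bhlhe40 (-1.18 ± 0.26) and Hao2 (-2.66 ± 0.65). With edgeR it called Bhlhe40 with no low-count filter and without WT female HFD replicate 5, and Hif1a without WT male chow replicate 1.

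The effect of HFD differed between the sexes at 85 genes, of which 53 had the higher response in males and 32 the lower. Female-biased genes were part of this difference, with 8 of 24 responding more upward in males and 1 more downward (adjusted p = 0.0232 with an estimated correlation and 0.00478 with fry). A more upward response in males can also come from a fall in females where males are near the floor. Levels of this kind were those of A1bg, from 1282 to 325 CPM in females and from 0.094 to 0.142 CPM in males. The count of 8 does not separate such cases from rises in males. Cyp2b9 had an interaction of 5.00 ± 0.75, adjusted p = 2.28e-04. Its mean went from 761 to 768 CPM in females and from 4.00 to 120.1 CPM in males. Abcd2 (2.79 ± 0.41, adjusted p = 1.62e-04) went from 103.1 to 137 CPM in females and from 5.41 to 41.1 CPM in males. Cyp2b13 (6.24 ± 0.88, adjusted p = 1.07e-04) went from 347 to 423 CPM in females and from 0.0320 to 4.15 CPM in males. Its male chow level rests on 6 reads in WT and 1 in KO libraries, so the size of its interaction is uncertain. Cyp2c40 (-2.43 ± 0.37, adjusted p = 3.20e-04) went from 610.4 to 390.4 CPM in females and from 8.5 to 0.997 CPM in males. Fam84b (1.09 ± 0.15, adjusted p = 7.72e-05) and the autophagy gene Atg16l2 (-1.40 ± 0.18, adjusted p = 1.84e-05) had the other interactions of smallest adjusted p. In WT males Atg16l2 went from 24.0 ± 4.63 to 7.96 ± 1.45 CPM, and in WT females from 5.68 ± 0.84 to 5.17 ± 0.76 CPM. Cholesterol genes had a median interaction of -0.54, with 1 of 23 called over all genes and 16 lower and 1 higher adjusted over the list alone (adjusted p = 0.276 with an estimated correlation). All 6 named genes kept their call whichever library was left out. The count was 41 at 2-fold or more and 176 with DESeq2, and fell to between 44 and 56 without any 1 of 14 libraries, with the lowest, 44, without WT female chow replicate 4.

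Between WT males and WT females on chow, most of the sex-biased liver genes tested differed. All 24 of 24 female-biased genes were lower in males, with Slc22a26 at 0.592 against 365 CPM. Of 26 male-biased genes 23 were higher in males, with Cyp2d9 (5.78 ± 0.29, adjusted p = 1.77e-18) and Mup20 (8.02 ± 0.45, adjusted p = 5.48e-17), a gene of a family of near-identical copies whose reads may have been divided. Both lists kept their calls (estimated correlation, adjusted p = 1.41e-07 and 6.01e-05). Alas2, of heme synthesis, was higher in males (3.17 ± 0.17) and the metallothionein Mt1 lower (-5.10 ± 0.65). Bile acid genes were higher in 7 cases, among them Cyp7b1 (3.42 ± 0.31), and lower in 3. Of the clock genes 7 of 20 were higher, among them Per2 (1.51 ± 0.22), and 3 lower. The labels give the same range of collection hours for all libraries, so a difference in hour between the sexes cannot be told apart. Nuclear respiratory chain genes were higher in 20 of 56 cases, including cytochrome c, Cycs (0.57 ± 0.07), with adjusted p = 0.578 with an estimated correlation. Over all genes 3692 differed, 1874 higher and 1818 lower in males, and 836 by 2-fold or more. Of 90 named genes, 78 kept their call whichever library was left out.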

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

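The search for libraries far from their group was run on the mitochondrial share, on Nnt and Xist, and on genes whose values had already been seen, and the test of Xist in males was chosen after the result was seen. The leave-one-out test of the diet by sex genes was planned.

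Single libraries stood apart in 21 of 184 checks of a value in a group of 5, on genes chosen after their values were seen. Chance alone gives about 1 in 20 for normally distributed values, which values near the floor are not. A single nonzero value among zeros, as for Cyp2b13, stands apart whatever its size, so an excess is not shown. The mitochondrial share was 4.02% in KO male chow replicate 3 (others 7.32% to 7.93%), 5.94% in WT female HFD replicate 2 (6.65% to 6.92%) and 7.24% in KO female HFD replicate 3 (6.96% to 7.02%). Xist stood apart in WT female chow replicate 4 (1655 CPM) and WT female HFD replicate 4 (1576 CPM). In males it did so in KO male chow replicate 3 (2.56 CPM, others at most 0.461) and KO male HFD replicate 5 (1.92 CPM, others at most 0.61). Lpl was at 141.9 CPM in WT female HFD replicate 2, the library without which its diet call was lost, and Cidec at 6.69 CPM in WT male chow replicate 3. Hsd17b13 was at 304 CPM in WT female chow replicate 2 and 275 CPM in WT male chow replicate 1. Vnn1 was at 80.1 CPM in KO female chow replicate 2 and 134 CPM in WT female HFD replicate 1. In KO female HFD replicate 5 the cholesterol genes Sqle (103.8 CPM, others 38.5 to 47.8) and Fdft1 (122 CPM, others 79.8 to 91.6) were both high, and Fdft1 was low in WT male HFD replicate 4 (44.8 CPM). Cyp2b13 had reads in 1 library each of WT male chow (replicate 3, 0.254 CPM) and KO male chow (replicate 1, 0.0662 CPM) and 0 in the others. Abcd2 was at 131 CPM in WT female chow replicate 4 and 3.8 CPM in KO male HFD replicate 2 (others 35 to 46.3). Fgf21 was at 11.8 CPM in KO male HFD replicate 5.

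The response to HFD differed between the sexes at 85 genes by the interaction test, among them Cyp2b13 (log2 6.24, from few male chow reads), Cyp2b9 (5.0), Abcd2 (2.79), Fam84b (1.09), Atg16l2 (-1.40) and Cyp2c40 (-2.43). Of 24 female-biased genes, 8 responded more upward in males, a count that does not separate rises in males from falls in females. Female liver RNA in the male HFD libraries is argued against, since Xist in them was 0.0350% of its level in females on HFD while Cyp2b9 was at 15.6%, and 14 of 24 female-biased genes were under 1%. Whether a few libraries set the result stays open. Cyp2b13, Cyp2b9 and Abcd2 kept their call in 40 of 40 fits that left out 1 library, but they are among the genes of smallest adjusted p and 1 library at a time does not test several, so that planned bound excluded too little. Cyp2b9 ran from 2.15 to 329.5 CPM over the male HFD libraries, the count of 85 fell to 44 without WT female chow replicate 4, and reads divided between the related Cyp2b genes stay open, as does an effect of the diet that differs by sex.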

How the results depend on the processing

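Of the alternatives here, the clock covariate, and the naming of KO male chow replicate 3, were chosen after results were seen. The others were planned.

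Diet and sex counts stayed above 0 under every alternative, and genotype counts stayed at or under 13. At 2-fold or more the counts were 126, 216, 382 and 192 for diet (WT females, KO females, WT males, KO males), 41 for diet by sex, 836 for sex and 0 for genotype in females on HFD, since the threshold removes smaller changes. With only the groups compared, diet gave 226 in WT females, 1024 in KO females, 1079 in WT males and 495 in KO males, so the count moved both ways, with 2751 for sex and 0 for genotype in females on HFD. With no low-count filter, genotype gave 0 in females on HFD and 2 in males on HFD, and genotype by sex gave 1. DESeq2 gave 1 in males on chow, 1 in the genotype mean, 13 for genotype by sex and 176 for diet by sex. The clock covariate gave 12 genes for genotype in males on chow, 1 in males on HFD and 9 for genotype by diet in males. The cause was not tested for these. The replicate numbers did not show a strong pairing of the samples. Of 140 same-number pairs 10 had a correlation above 0.1, with a median of 0.0095 against -0.0041 for other numbers. Of 40 libraries 12 correlated best with their own number. No chance level was drawn for these values, so a weak pairing stays open. With the replicate block, the counts were 418, 751, 1798 and 678 for diet, 69 for diet by sex, 3673 for sex, 1 (Ttbk2) for genotype in females on HFD and 0 for the other genotype results.

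Leaving out 1 library at a time gave 0 to 0 for genotype in females on chow, males on chow and the mean, 0 to 1 in females on HFD (lost without WT female HFD 2, 3 or 4, or KO female HFD 1, 3 or 4) and 0 to 6 in males on HFD (2 without WT replicate 2, 6 without WT replicate 4). It gave 234 to 534 for diet in WT females (234 without WT female HFD 2, 289 without WT female chow 5), 516 to 774 in KO females, 1241 to 2313 in WT males and 441 to 854 in KO males (441 without KO male HFD 5, 462 without KO male HFD 3). Genotype by diet gave 0 to 0 in females and 0 to 1 in males (1 without WT male chow 4), genotype by sex 0 to 1 (1 without WT female HFD 5 or WT male chow 1), diet by sex 44 to 114 and sex 3103 to 3749. Diet by sex was 55 without WT female chow 3, 44 without WT female chow 4, 47 without KO female chow 2, 53 without KO female chow 5, 48 without KO female HFD 2 and 56 without KO female HFD 3. It was 55, 55 and 50 without WT male chow 1, 2 and 5, 55 without KO male chow 4, 56 and 55 without WT male HFD 3 and 5, and 55 and 54 without KO male HFD 3 and 5. Without KO male chow replicate 3 diet in KO males gave 496 and diet by sex 57. The KO minus WT difference of Nnt in females on chow (0.03) turned to -0.07 without WT female chow 3, -0.14 without WT female chow 5 and -0.12 without KO female chow 5, with the highest, 0.20, without WT female chow 4. In females on HFD (-0.12) it turned to 0.043 without KO female HFD 1, with the lowest, -0.21, without KO female HFD 2. None of these was called. Of the named genes' values with 1 library left out, 3178 kept direction and call, 298 kept direction only and 4 reversed. Direction was kept with the call lost for 26 with no filter, 42 with only the groups compared, 8 with the block, 2 with DESeq2, and 1 each with RLE, the strict filter and the clock covariate. At this depth half-widths of the 95% interval had a median of 0.30 for a contrast of 2 groups and 0.15 for the genotype mean over all genes tested, and genes of smaller spread were called at smaller differences.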

Other observations

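The tests of collection time, of precision and of exchanged labels below were chosen after the result was seen. The tests of nested gene models and of other splits of the samples were planned.

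Markers of other liver cells moved with HFD in some groups. In WT males 8 of 22 stellate cell and matrix genes rose, among them Col3a1 (0.84 ± 0.18), Col6a1 (0.74 ± 0.14) and Reln (0.64 ± 0.14), with adjusted p = 0.106 with an estimated correlation, and 0 rose in the other 3 diet comparisons. Lipid-associated macrophage and inflammation markers rose in 5 of 13 cases in WT males, with Trem2 at 2.64 ± 0.59 and the macrophage elastase Mmp12 at 3.10 ± 0.63 (adjusted p = 0.223 with an estimated correlation), in 2 in KO females, where Mmp12 had 3.58 ± 0.57, in 1 in WT females and in 0 in KO males. Between genotypes these counts are not shown to differ, since the genotype by diet interaction called 0 genes in either sex. For the difference in diet response between the sexes, 0 stellate and 0 lipid-associated macrophage genes were called higher in males and 0 and 0 lower (camera adjusted p = 8.30e-04 and 0.564, and 0.384 and 0.865 with an estimated correlation). The endothelial marker Lyve1 rose in WT females (1.12 ± 0.22) and WT males (0.82 ± 0.22). In KO males 1 of 16 endothelial markers rose. A difference from KO is not shown for Lyve1, since the genotype by diet interaction called 0 genes. Of 18 macrophage markers 2 rose in WT females and 2 in WT males, 0 changed in KO females and 2 fell in KO males, among them Lyz2 (-0.56 ± 0.13), the 1 of these 6 calls kept whichever library was left out. Bile duct, neutrophil, pancreas and skeletal muscle markers had at most 1 called gene in each direction in the diet comparisons. Of 5 adipose markers 3 rose and 1 fell in WT males, 2 rose in KO males, 1 in KO females and 0 in WT females. Cfd rose in WT males (2.78 ± 0.68) and KO males (3.71 ± 0.82), Fabp4 in WT males (0.76 ± 0.17), and Cidec, which is also in the lipid droplet list, in both. Macrophage markers were lower in WT males than in WT females on chow in 12 of 18 cases, including Vsig4 (-1.23 ± 0.16) and Clec4f (-0.79 ± 0.13), with adjusted p = 0.298 with an estimated correlation.

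Acute-phase genes rose in 9 of 23 cases and fell in 1 on HFD in WT males, with lipocalin 2, Lcn2 (2.76 ± 0.63), and Il1rn (1.61 ± 0.37) higher and Orm1 (-0.66 ± 0.16, not called when only those groups entered the fit) lower (adjusted p = 0.597 with an estimated correlation). In KO females 3 rose, including Il1rn (1.35 ± 0.34). The stress hormone gene Gdf15 rose in WT males (1.61 ± 0.37), within an ATF4 and mitochondrial stress list of 26 in which 3 rose and 5 fell. The interferon gene Ifi27l2b rose in WT males (1.73 ± 0.30) and KO males (1.59 ± 0.32) while 2 of 26 of its list rose and 2 fell in WT males. Hmgcs1, which is within 5 Mb of Nnt and belongs to the cholesterol genes, fell in WT females (-1.22 ± 0.22), WT males (-1.35 ± 0.22) and KO males (-1.17 ± 0.22).

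Nnt was near the floor in WT libraries too. Reads shared by overlapping models may have been left out of the counts, because 16 of 16 protein-coding models (100%) lying wholly inside another gene's exons on the same strand had 0 reads in all 40 libraries, against 5 of 66 (7.58%) lying in introns. On the opposite strand it was 10 of 11 (90.9%) inside exons, against 20 of 220 (9.09%) in introns. The second Nnt model covers 3339 of the first model's 7037 exonic bases in the annotation used here, so in that annotation the remaining bases could still be counted, and how far the loss reaches in the authors' annotation is open. Exchanged genotype labels cannot be told apart from correct ones, since the highest Nnt value in any library was 2.13 CPM and no group stands out.

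Few genes differed between the genotypes as labelled. Nnt itself was alike in WT and KO libraries, so the counts do not show that the groups differed in functional NNT. Whether the few calls reflect that, or a small effect of its loss, stays open. Changes of 2-fold or more in the mean over the 4 strata hidden by low precision are argued against for most genes, since the 95% interval of the mean reached 2-fold for 2.73% of tested genes (427 of 15627). Whether a spread in collection time hides a genotype effect cannot be told apart from how the clock score was made. With the score as a covariate 0 genes were called in the mean, where opposite changes cancel, but 12 in males on chow (7 of them clock genes that make up the score), 1 in males on HFD and 9 for genotype by diet in males (6 of them clock genes), with Dbp at -2.46 ± 0.24 in males on chow and 1.38 ± 0.22 in males on HFD. The score, the only such covariate tried, was built after seeing Dbp range from -1.18 to 5.48 log2 CPM, holds 69.5% of the variance of 20 clock genes within groups and removes that spread only.

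Other splits of the same libraries were drawn 100 times per result, the real split included. For diet, only the real split reached the real count in each comparison (1 of 100), the smallest share that 100 splits can give. The counts were 438 against at most 10 in WT females, 772 against 5 in KO females, 1811 against 223 in WT males and 695 against 7 in KO males. The real count was also the largest for sex (1 of 100, 3692 against 1612), where splits that part 4 libraries of a sex from 1 still carry the sex difference. For diet by sex it was 85 against at most 1 (1 of 100). Those splits mix the diets within each group, so they remove the diet effect itself and add it to the spread. They therefore do not test the difference between the sexes alone. For the single genotype call, in females on HFD, chance cannot be excluded (12 of 100 splits, the highest other at 9). For the other genotype results the real count is 0, which 100 of 100 splits reach whatever the data, so the splits say nothing about chance there. The highest other split gave 8 in females on chow, 159 in males on chow, 45 in males on HFD and 8 in the mean, and 11, 83 and 9 for genotype by diet in females, in males and genotype by sex. In males on chow 17 other splits gave any call and for genotype by diet in males 7 did. The highest splits, with 159 and 83 calls, may point to a structure of the samples, which was neither tested nor identified.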
